A study of Mus musculus with 12 samples.

How the data were processed

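RNA from all cells of the mandibular condylar fibrocartilage, with RNA integrity numbers of at least 9 per the labels, was enriched for polyadenylated transcripts and sequenced as 100-base reads on Illumina HiSeq instruments. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17 and aligned with TopHat to mouse genome build mm9. The TopHat version, the counting tool, the gene annotation and the treatment of reads with several matches were not given in the sources used here. The deposited raw table held counts per gene symbol for 23284 genes and 12 libraries. The normalized table held a signal per gene that the authors obtained by dividing counts by a size factor per library. The authors' 6 deposited comparison tables held log2 fold changes with their standard errors, and p-values unadjusted and adjusted, in the column layout of DESeq2 per the file headers. Reference coordinates served only to group the guanylate-binding protein (Gbp) genes by chromosome, and these groups are called neighbourhoods below. The strand of the libraries was not given, so genes that overlap on opposite strands can share counts. Of the symbols, 20882 were found among current names of GENCODE M21 and 23086 with older names included.

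Samples were grouped by the genotype and treatment in their labels, and these groups, the comparisons, the gene lists, the naming rule and the other settings to be tried were fixed before the data were examined. Genes were tested if they passed the group-wise expression filter of edgeR with a minimum count of 10, which kept 14832, and 4326 had no count in any library. Counts were scaled by trimmed mean of M values and fitted in edgeR 4.0.16 under R 4.3.3 with a quasi-likelihood negative binomial model with 1 mean per group over all 12 libraries, leaving 8 residual degrees of freedom. The biological coefficient of variation was 25.9%. Contrasts were the E2 effect in WT, the E2 effect in ERalphaKO, the genotype effect under placebo, the genotype effect under E2, and the difference of the E2 effect between genotypes. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Standard errors of edgeR fold changes were calculated back from the F statistic of the same fit. Each is the absolute log2 fold change divided by the square root of F. Those of list medians come from the spread over list members, which are not independent replicates. Values of log2 CPM used a prior count of 2, and CPM in the text are group means ± SD or single libraries. With 1 to 3 counts in a group, ratios carry a 95% counting interval, and with 0 counts a floor from 3 counts. These intervals and floors cover counting error alone, without the spread between libraries, and reads were not collapsed by molecular identifiers.

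The named genes were Esr1, then the 10 largest positive and 10 largest negative changes among genes past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the 2 groups compared, the last of these not asked of the interaction. From each gene list up to 4 members past the threshold followed by p, or, where there was none, up to 2 of the most expressed members as values. Predicted genes were not named, and 1 for E2 in WT and 2 for genotype under E2 met the conditions other than size. The 27 lists had 446 members, of which 400 were tested. They were cartilage matrix and chondrocyte, fibrous matrix, hypertrophy and mineralization, matrix proteases and inhibitors, Wnt target genes, Wnt ligands and antagonists, TGF-beta and BMP signalling, hedgehog and PTHrP, inflammatory and NF-kB, interferon response, estrogen-responsive, sex steroid receptors and steroid metabolism, insulin-like growth factor axis, cell cycle, and immediate-early and dissection stress. The 12 marker lists covered skeletal muscle, osteoblast and osteocyte, osteoclast, erythroid, granulocyte, macrophage, lymphocyte, endothelial, adipocyte, epithelium, salivary gland and peripheral nerve. Some lists shared members: 5 of 15 hypertrophy genes, 5 of 19 estrogen-responsive genes and 3 of 14 osteoblast markers also stood in another list. In WT placebo libraries a mean of at least 1 CPM was reached by all 14 macrophage, all 19 muscle and 10 of 14 granulocyte markers, but by 1 of 13 lymphocyte markers. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with a correlation estimated from the data, and with fry in 2 forms, directional and, for members that change either way, mixed. Either form of fry tests a list by itself, so a few changed members can be enough for the mixed one to pass.

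The scripts were tested on simulated data with 200 genes changed by 2-fold or 4-fold. Apart from the changes, simulated genes varied independently around 1 mean shared by all groups, without admixture of other tissue. The share recovered was 52.5% and 74.0% for E2 in WT, 55.0% and 89.8% for E2 in ERalphaKO, 51.0% and 85.9% for genotype under placebo, 46.5% and 86.9% for genotype under E2, and 21.2% and 64.6% for the interaction. False calls made up 3.82%, 4.67%, 2.16%, 4.35% and 5.56% of calls in the same order. Libraries were checked for duplication, and the lowest chi-square per degree of freedom between replicates was 18.9. Settings fixed in advance were DESeq2 1.42.0, its size factors within edgeR, no expression filter, robust estimation, the libraries of the 2 groups alone, a replicate block, a skeletal muscle marker covariate, and omission of each library in turn. When 1 WT placebo library was left, it was assumed to vary like the other groups. Settings chosen after seeing the data were muscle and granulocyte covariates together, limma voom with library weights, and omission of the 2 libraries with the highest granulocyte marker level. The authors' deposited tables of groups that differ in both genotype and treatment were used for counts of genes alone.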

Results

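Gene expression was measured by RNA sequencing of polyadenylated RNA in mandibular condylar fibrocartilage, the tissue that covers the condyle of the jaw joint, with all of its cells included. The animals were female C57BL/6 mice, ovariectomized at 16 weeks of age to remove the main source of estrogen and sampled 1 week later, at 17 weeks. During that week they carried a pellet with placebo or with 0.01 mg of 17β-estradiol (E2). The E2 pellet had a release time of 60 days, so 0.01 mg is its content and not the dose of that week. The 12 libraries formed 4 groups: wild-type (WT) under placebo (n = 2), WT under E2 (n = 3), estrogen receptor alpha knockout (ERalphaKO) under placebo (n = 4) and ERalphaKO under E2 (n = 3). The comparisons addressed which genes E2 regulates in this tissue and which of these effects pass through estrogen receptor alpha.

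Total counts, in M (the SI prefix mega), were 17.4 and 28.8 M in WT placebo replicates 1 and 2, and 19.3, 21.6 and 19.3 M in WT E2 replicates 1 to 3. ERalphaKO placebo replicates 1 to 4 held 16.5, 22.1, 24.5 and 25.2 M, and ERalphaKO E2 replicates 1 to 3 held 16.3, 9.70 and 19.9 M. A gene with 3 counts stood at 0.309 CPM (counts scaled to library size) in the smallest library and at 0.104 CPM in the largest. The first principal component held 34.6% of the variance and ran from 77.8 in ERalphaKO placebo replicate 3 over 49.65 in ERalphaKO E2 replicate 1 to -50.84 in WT E2 replicate 2. In the same order these libraries had the 2 highest and the lowest mean log2 CPM of granulocyte markers, 9.268, 6.923 and -1.924. Values are given with gene symbols as deposited, which was the only identifier used. The labels do not state that replicates came from separate animals, so p-values cover the spread between these samples.

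Esr1, the gene for estrogen receptor alpha, stood at 17.5 and 14.2 CPM in WT placebo replicates 1 and 2 and at 10.6, 8.5 and 12 CPM in WT E2 replicates 1 to 3. It stood at 3.7, 5.7, 4.0 and 5.1 CPM in the 4 ERalphaKO placebo libraries and at 5.7, 5.8 and 4.5 CPM in the 3 ERalphaKO E2 libraries. All 7 ERalphaKO libraries lay below all 5 WT libraries. Which part of Esr1 the knockout removed was not given in the sources used here, so transcript counts cannot show how much functional receptor remained. Under placebo Esr1 was 3.42-fold lower in ERalphaKO (log2 fold change -1.77 ± 0.20 SE, adjusted p = 0.0252). Under E2 its genotype difference was -0.97 ± 0.20 (adjusted p = 0.0549), and its change with E2 was -0.61 ± 0.22 in WT (adjusted p = 0.467) and 0.20 ± 0.19 in ERalphaKO (adjusted p = 0.991), none of which passed the test.

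**Figure D1:**
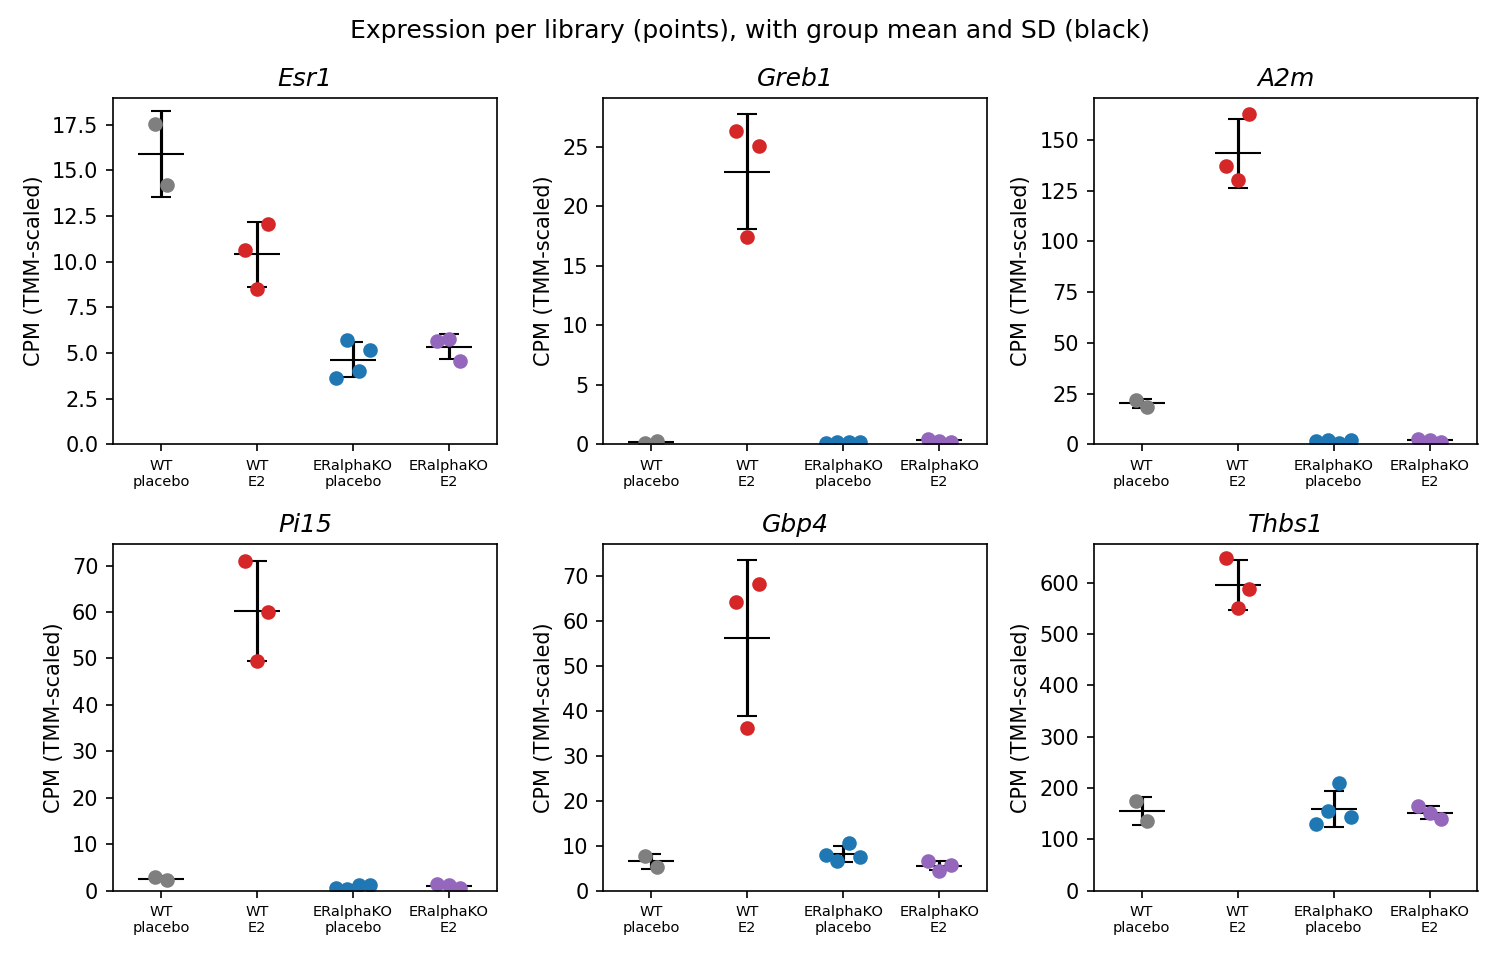
Each dot is 1 library, with the group on the horizontal axis and CPM on the vertical axis for Esr1, Greb1, A2m, Pi15, Gbp4 and Thbs1; the horizontal mark and bar are the group mean ± SD. Greb1 averaged 22.9 CPM in WT libraries under E2 and between 0.164 and 0.334 CPM in the other groups, and A2m was low in every ERalphaKO library.

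With E2 in WT fibrocartilage, 55 genes rose and 13 fell (3 against 2 libraries, 14832 genes tested). Greb1, an estrogen-induced gene whose product is a cofactor of the estrogen receptor, rose 112-fold from 0.187 ± 0.0984 to 22.9 ± 4.80 CPM (SD), a log2 fold change of 6.81 ± 0.41 (SE, adjusted p = 8.74e-05). Pi15, a secreted peptidase inhibitor, rose 24.0-fold (4.59 ± 0.43, adjusted p = 0.00318), and Trpc6, a calcium-permeable cation channel, rose 16.8-fold (4.07 ± 0.39, adjusted p = 0.00318). Sftpa1, a collagen-like lectin known from lung surfactant, rose 100-fold (6.65 ± 0.73, adjusted p = 0.00394). Gbp8, one of the interferon-inducible guanylate-binding GTPases, rose 29.9-fold (4.90 ± 0.50), the kinase gene Ripk4 30.7-fold (4.94 ± 0.66), the unconventional myosin gene Myo5c 14.0-fold (3.81 ± 0.48) and the macrophage lectin gene Mgl2 14.0-fold (3.81 ± 0.68, adjusted p = 0.0437). The secreted neuronal protein gene Lgi2 and the pacemaker channel gene Hcn4 rested on 2 and 1 counts in the placebo libraries. Their count ratios were 281 (95% counting interval 77.6 to 2330) and 119 (21.1 to 4730), with adjusted p = 0.0047 and 0.0419.

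Among the 13 genes that fell with E2 in WT, Limch1, which regulates actomyosin contraction, changed most, by -2.06 ± 0.26 on the log2 scale, from 153 to 36.8 CPM (adjusted p = 0.00780). Slc20a2, a sodium-phosphate cotransporter, fell from 116 to 51.6 CPM (-1.17 ± 0.14, adjusted p = 0.00666). Slc16a3, a lactate exporter, changed by -0.72 ± 0.11 and the ketone body enzyme gene Bdh1 by -0.83 ± 0.13. Hunk (-1.58 ± 0.27), Tmem178 (-1.56 ± 0.27), D4Bwg0951e (-1.39 ± 0.24), Wfdc1 (-1.29 ± 0.24), the long pentraxin gene Ptx3 (-1.29 ± 0.23) and Megf6 (-0.95 ± 0.14) also fell, with adjusted p between 0.0182 for Megf6 and 0.0495 for Wfdc1. Several called genes outside the naming rule were chosen after their values were seen. A2m, a broad protease inhibitor, rose from 20.1 to 143 CPM (2.84 ± 0.32, adjusted p = 0.00394), Thbs1, the matricellular thrombospondin-1, from 155 to 596 CPM (1.94 ± 0.20), and the scaffold protein gene Whrn from 29.2 to 95.3 CPM (1.71 ± 0.18, adjusted p = 0.00344 for both). Gbp4 (3.12 ± 0.33), Gbp6 (2.78 ± 0.46) and Gbp9 (1.92 ± 0.31) rose beside Gbp8. Values for Gbp6 and for the uncalled Gbp10 (5.11 ± 1.22) are uncertain, since close paralogs share sequence with them.

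Greb1 kept its call without any one of the 12 libraries. Gbp8, Pi15, Trpc6 and Thbs1 lost theirs without WT placebo replicate 2, and Lgi2, Sftpa1, Ripk4, Myo5c, Limch1, Slc20a2, A2m, Whrn and Gbp4 lost theirs without either WT placebo library. The other named calls were kept in between 1 and 9 of the 12 omissions. Of the 22 calls that the naming rule gave, 4 and 1 were kept without WT placebo replicates 1 and 2, 10, 19 and 10 without WT E2 replicates 1 to 3, 14, 14, 19 and 12 without ERalphaKO placebo replicates 1 to 4, and 15, 14 and 12 without ERalphaKO E2 replicates 1 to 3. Genes higher numbered 5 without WT placebo replicate 1, 1 without WT placebo replicate 2, and 17, 113 and 21 without WT E2 replicates 1, 2 and 3. They numbered 34, 31 and 27 without ERalphaKO placebo replicates 1, 2 and 4, and 31, 33 and 23 without ERalphaKO E2 replicates 1, 2 and 3. Genes lower numbered 0 without WT placebo replicate 1 or 2 by edgeR, where 744 and 799 genes had an unadjusted p under 0.05. They numbered 3 and 5 without WT E2 replicates 1 and 3, 7, 7 and 4 without ERalphaKO placebo replicates 1, 2 and 4, and 6, 4 and 4 without ERalphaKO E2 replicates 1, 2 and 3. DESeq2 called 157 genes higher and 90 lower, with all 68 of the edgeR calls among them, and a fit to the 5 WT libraries alone called 7 genes higher. With the muscle marker level as a covariate edgeR called 36 higher and 9 lower, 34 and 5 of them among the 68.

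Among the skeletal gene lists in WT under E2, single called members were Adamts5, an aggrecan-cleaving protease (1.94-fold higher, 0.96 ± 0.17, adjusted p = 0.0437), and the ligand gene Wnt4 (2.01-fold higher, 1.00 ± 0.17, adjusted p = 0.0419). In the cartilage matrix list, 2 of 20 members were higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.18 (adjusted p = 0.617; adjusted p = 0.846 with an estimated correlation). Its most counted member Col2a1, the main cartilage collagen, gave 0.58 ± 0.59. The hypertrophy and mineralization list had a median of 0.24, with 2 of 15 members higher when adjusted over the list alone (adjusted p = 0.0386; adjusted p = 0.793 with an estimated correlation). Its bone sialoprotein gene Ibsp gave 0.98 ± 0.25 (adjusted p = 0.198). The fibrous matrix list lay lower, with a median of -0.27 and 0 of 26 members passing over the list alone (adjusted p = 0.00586; adjusted p = 0.696 with an estimated correlation). By edgeR 7 of those 26 had an unadjusted p under 0.05, DESeq2 called 0, and Col1a1 gave -0.49 ± 0.17. Without WT E2 replicate 3 the fibrous matrix call ended (adjusted p = 0.0657), and so did the hypertrophy call (median 0.08, adjusted p = 0.374), which also ended without either WT placebo library (adjusted p = 0.0728 and 0.0835). The osteoblast and osteocyte markers had a median of 0.06 (1 of 14 higher when adjusted over the list alone, adjusted p = 0.159; adjusted p = 0.837 with an estimated correlation) and the osteoclast markers -0.05 (adjusted p = 0.657; adjusted p = 0.846 with an estimated correlation). Over the 12 libraries the mean log2 CPM was 7.449 to 8.166 for osteoblast and osteocyte markers and 7.596 to 8.118 for osteoclast markers. It was 5.597 to 7.783 for the cartilage matrix list. Beyond these markers, bone carried into the samples was not tested.

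Among lists of signalling and regulation with E2 in WT, matrix proteases and inhibitors had a median of -0.06 (1 of 20 higher when adjusted over the list alone, adjusted p = 0.707), Wnt ligands and antagonists 0.02 (1 of 19 higher, adjusted p = 0.813), TGF-beta and BMP signalling 0.08 (1 higher and 1 lower of 24, adjusted p = 0.515) and hedgehog and PTHrP 0.21 (adjusted p = 0.617), each with adjusted p = 0.846 with an estimated correlation. Wnt target genes lay at -0.16 with 1 of 14 lower when adjusted over the list alone (adjusted p = 0.0159; adjusted p = 0.608 with an estimated correlation). That call ended without WT placebo replicate 1 (adjusted p = 0.170) and without WT E2 replicate 3 (adjusted p = 0.0618), and the median was -0.27 without WT placebo replicate 2 or WT E2 replicate 2. The insulin-like growth factor axis lay at -0.23, with 2 of 15 lower when adjusted over the list alone (adjusted p = 0.0417; adjusted p = 0.364 with an estimated correlation). Igf1, itself an estrogen target in other tissues, gave -1.22 ± 0.26 (adjusted p = 0.103). The axis lost its call without WT placebo replicate 1 or 2 (adjusted p = 0.0728 and 0.0535) and without WT E2 replicate 2 or 3 (median -0.07 and -0.17, adjusted p = 0.180 and 0.0643). Without WT E2 replicate 1 its median was -0.35. In the estrogen-responsive list 3 of 19 members were higher and 2 lower when adjusted over the list alone, with a median of 0.24 (adjusted p = 0.00817; adjusted p = 0.364 with an estimated correlation). Of these, Greb1 alone passed over all genes, and the progesterone receptor gene Pgr gave 3.01 ± 0.75 (adjusted p = 0.176). The estrogen-responsive call ended without WT placebo replicate 1 (adjusted p = 0.0944) and without WT E2 replicate 3, where the median was 0.02 (adjusted p = 0.0909). Sex steroid receptors and steroid metabolism had a median of -0.20 and a mean of 0.24 (1 of 9 higher when adjusted over the list alone, adjusted p = 0.754; adjusted p = 0.846 with an estimated correlation), and inflammatory and NF-kB genes a median of 0.28 (adjusted p = 0.111; adjusted p = 0.811 with an estimated correlation).

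Of 14 macrophage markers, 13 had positive fold changes with E2 in WT and 7 were higher when adjusted over the list alone, with a median of 0.79 (adjusted p = 2.64e-09; adjusted p = 0.364 with an estimated correlation). Among them the complement genes C1qa and C1qb gave 0.87 ± 0.27 and 1.15 ± 0.28, and the mannose receptor gene Mrc1 0.95 ± 0.26, none called over all genes. By edgeR 8 of the 14 had an unadjusted p under 0.05, and DESeq2 called 5. Without WT E2 replicate 3 the macrophage median was 0.52 and the call remained. The interferon response list had 17 of 18 members positive and a median of 0.57 (adjusted p = 2.4e-04; adjusted p = 0.764 with an estimated correlation). Without WT E2 replicate 3 it had a median of 0.16 and no call (adjusted p = 0.121). All 12 endothelial markers were positive, with a median of 0.38 (adjusted p = 3.06e-04; adjusted p = 0.743 with an estimated correlation), and without WT E2 replicate 3 the call ended (median 0.18, adjusted p = 0.0643). The endothelial median was 0.23 without WT placebo replicate 2 and 0.57 without WT E2 replicate 2. All 25 cell cycle genes were negative, with a median of -0.39 (adjusted p = 2.2e-06; adjusted p = 0.749 with an estimated correlation). Mki67, a proliferation marker, gave -0.32 ± 0.31. Without WT E2 replicate 2 the median was -0.23 and the call remained. The immediate-early and dissection stress list lay at -0.37 (adjusted p = 0.00438; adjusted p = 0.811 with an estimated correlation) and turned to 0.06 without WT placebo replicate 2 (adjusted p = 0.489) and to -0.67 without WT placebo replicate 1. Over all genes, 24 of the 27 lists held no member called by edgeR, while 58 of their 337 members had an unadjusted p under 0.05 and DESeq2 called 18. Directional fry called 0 lists, and mixed fry called 7, with the estrogen-responsive list at adjusted p = 3.14e-08.

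Of 8 lists that mark other tissues or blood, the adipocyte list alone passed for E2 in WT with the preset correlation. Adipocyte markers lay at -4.25, with 6 of 9 lower when adjusted over the list alone (adjusted p = 3.16e-05; adjusted p = 0.364 with an estimated correlation). Without WT placebo replicate 2 they lay at -0.16 (adjusted p = 0.0946). Skeletal muscle markers had a median of -0.88 while the test pointed up (adjusted p = 0.397; adjusted p = 0.846 with an estimated correlation). Their mean log2 CPM was -0.62 and 6.74 in the WT placebo libraries and 5.64, 4.81 and 3.66 in the WT E2 libraries. Granulocyte markers had a median of 0.91 while the test pointed down (adjusted p = 0.113; adjusted p = 0.846 with an estimated correlation), with mean log2 CPM of 3.38 and 0.73 under placebo and of -1.51, -1.92 and 4.31 under E2. Erythroid markers lay at -1.78 (adjusted p = 0.111; adjusted p = 0.811 with an estimated correlation) and lymphocyte markers at 0.28 (adjusted p = 0.763; adjusted p = 0.882 with an estimated correlation). Peripheral nerve markers lay at -0.14 with 1 of 11 lower when adjusted over the list alone (adjusted p = 0.373; adjusted p = 0.811 with an estimated correlation). Epithelial markers lay at -0.09 with 1 of 5 higher when adjusted over the list alone (adjusted p = 0.803) and the 3 salivary gland markers at 0.28 (adjusted p = 0.657), both with adjusted p = 0.846 with an estimated correlation.

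**Figure D2:**
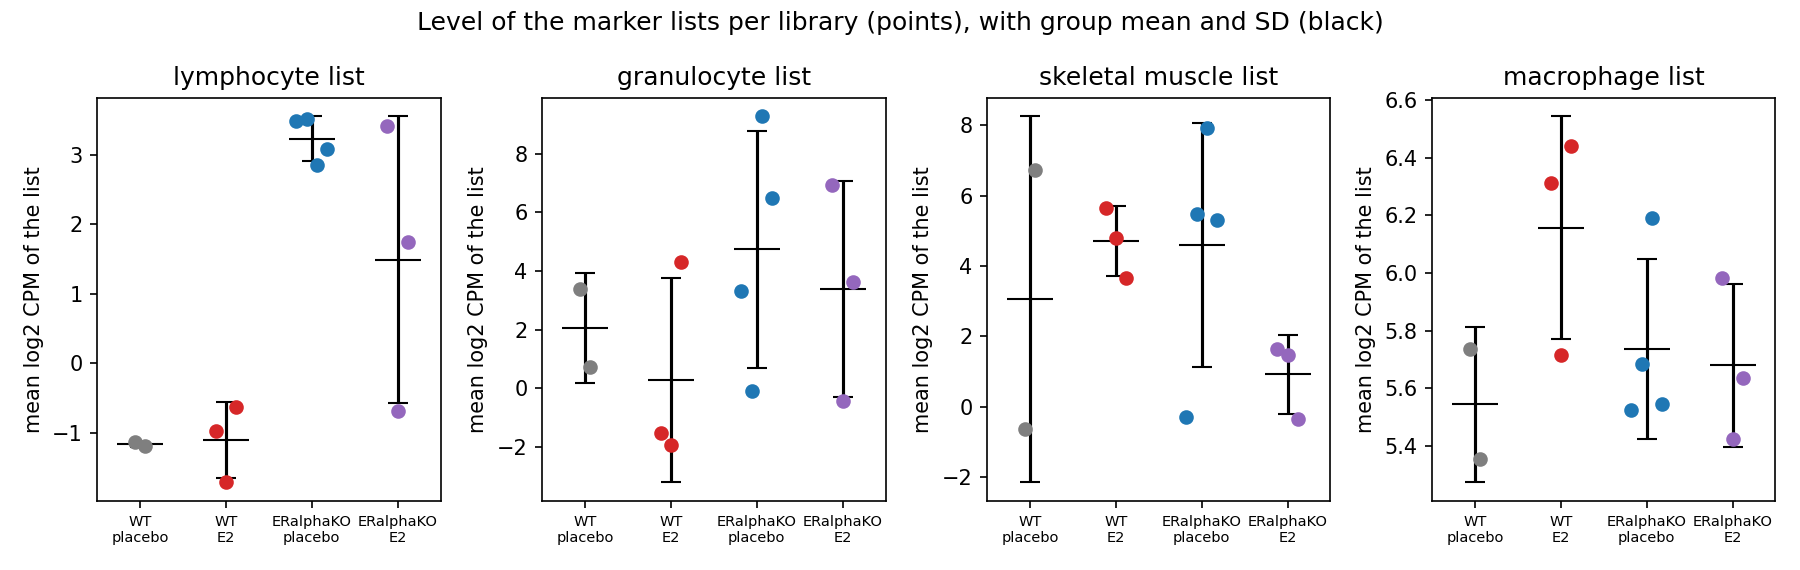
Each dot is 1 library, with the group on the horizontal axis and the mean log2 CPM of a marker list on the vertical axis, for lymphocyte, granulocyte, skeletal muscle and macrophage markers; marks and bars are the group mean ± SD. Lymphocyte markers lay between -1.72 and -0.63 in the WT libraries and between -0.70 and 3.51 in the ERalphaKO libraries, and muscle and granulocyte markers varied widely within groups.

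In ERalphaKO fibrocartilage the same treatment gave no gene past the threshold (3 against 4 libraries). By edgeR 0 genes were higher and 0 lower, 846 had an unadjusted p under 0.05 where 742 were expected by chance, and DESeq2 called 1 gene higher and 4 lower. Greb1 stood at 0.164 CPM under placebo and 0.334 CPM under E2 in ERalphaKO, Pi15 at 0.794 and 1.03 CPM, and A2m at 1.68 and 1.91 CPM. Thbs1 gave -0.07 ± 0.16 and Whrn 0.03 ± 0.14 on the log2 scale. On simulated counts with 200 changed genes, the same test found 55.0% of 2-fold changes and 89.8% of 4-fold changes in this comparison. Simulated genes varied independently and without admixture of other tissue, so these shares do not carry over to the real libraries. In the real comparison 18 of 19 skeletal muscle markers had an unadjusted p under 0.05 at a median of -5.81, with 0 called. The absence of calls therefore does not exclude changes of 4-fold.

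For E2 in ERalphaKO 7 lists passed with the preset correlation, and 0 with an estimated correlation or by directional or mixed fry. All 25 cell cycle genes were negative, with a median of -0.56 and 10 lower when adjusted over the list alone (adjusted p = 1.63e-21; adjusted p = 0.268 with an estimated correlation), among them Top2a, the mitotic topoisomerase gene, at -0.78 ± 0.25. Without ERalphaKO placebo replicate 3, which had the highest cell cycle and granulocyte scores of all libraries (5.126 and 9.268), the cell cycle median was -0.34 and the call remained. Granulocyte markers lay at -1.69 in the same comparison, with 2 of 14 positive, and did not pass (adjusted p = 0.069; adjusted p = 0.820 with an estimated correlation). By edgeR 0 of these 14 were called, 5 had an unadjusted p under 0.05 and DESeq2 called 0. Skeletal muscle markers lay at -5.81 with 18 of 19 lower when adjusted over the list alone (adjusted p = 6.35e-19; adjusted p = 0.268 with an estimated correlation). Their mean log2 CPM was -0.28, 5.49, 7.92 and 5.30 under placebo and 1.64, 1.47 and -0.36 under E2. All 14 osteoblast and osteocyte markers were positive with a median of 0.19 and 1 higher when adjusted over the list alone (adjusted p = 9.8e-08; adjusted p = 0.268 with an estimated correlation), and osteocalcin, Bglap, gave 0.44 ± 0.14. Lymphocyte markers lay at -1.24 (adjusted p = 4.61e-07; adjusted p = 0.268 with an estimated correlation), at -2.95 without ERalphaKO E2 replicate 1 and at -0.71 without ERalphaKO E2 replicate 2. TGF-beta and BMP signalling (median 0.12), interferon response (-0.27) and adipocyte markers (-1.11) also passed, with adjusted p = 0.0165, 0.0283 and 0.0124, and with adjusted p = 0.338, 0.820 and 0.558 with an estimated correlation. Those 3 calls ended without ERalphaKO placebo replicate 3 (median 0.05, 0.05 and -0.48, adjusted p = 0.273, 0.914 and 0.278) and without ERalphaKO E2 replicate 3 (adjusted p = 0.0815, 0.0815 and 0.12), and the last 2 also without ERalphaKO E2 replicate 2 (median -0.17 and -0.88, adjusted p = 0.238 and 0.0883). The interferon median was -0.42 without ERalphaKO placebo replicate 2, and the adipocyte median -2.07 without ERalphaKO E2 replicate 1. By edgeR 0 of the 386 list members was called over all genes, 47 had an unadjusted p under 0.05 and DESeq2 called 1.

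The genotype comparison under placebo asked what the loss of estrogen receptor alpha changes without hormone (4 against 2 libraries). A2m was 12.1-fold lower in ERalphaKO, at 1.68 against 20.1 CPM (-3.59 ± 0.29, adjusted p = 0.00179), and kept its call without any one library. In a fit to the libraries of the 2 groups alone the A2m call ended (adjusted p = 0.0536), and edgeR called 0 genes, with 1314 at an unadjusted p under 0.05. With the replicate block the A2m call ended too (adjusted p = 0.0782). Esr1 itself was the other gene called, and lost its call without either WT placebo library, WT E2 replicate 1 or ERalphaKO placebo replicates 1, 3 or 4. By edgeR 0 genes were higher, 1325 genes had an unadjusted p under 0.05, and DESeq2 called 123 higher and 27 lower. Single omissions left 2 genes higher without ERalphaKO E2 replicate 1 and 1 without ERalphaKO E2 replicate 2. Without ERalphaKO placebo replicate 3 and ERalphaKO E2 replicate 1, the pair with the highest granulocyte marker level, a setting chosen after the data were seen, edgeR called 52 genes higher and 5 lower.

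Lymphocyte markers were higher in the ERalphaKO placebo libraries, with a median log2 fold change of 4.94 and 12 of 13 members higher when adjusted over the list alone (adjusted p = 1.35e-25; adjusted p = 0.0608 with an estimated correlation). A self-contained rotation test, fry, called this list too (adjusted p = 0.0306). Cd79b, a subunit of the B cell receptor, stood at 0.561 ± 0.119 CPM in WT and 41.2 ± 20.1 CPM in ERalphaKO under placebo (6.21 ± 1.31, adjusted p = 0.330). Igj, the immunoglobulin joining chain gene, stood at 26.4 and 111 CPM. By edgeR 0 of the 13 passed over all genes, 12 had an unadjusted p under 0.05 and DESeq2 called 11. Granulocyte markers were all positive too, with a median of 5.67 (adjusted p = 0.00323; adjusted p = 0.547 with an estimated correlation), but without WT placebo replicate 2 (median 4.77, adjusted p = 0.159) or ERalphaKO placebo replicate 3 (median 3.13, adjusted p = 0.164) the call ended. Mean log2 CPM of the granulocyte markers was 3.38 and 0.73 in the WT and 3.32, -0.10, 9.27 and 6.48 in the ERalphaKO placebo libraries.

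Cartilage matrix genes lay lower in ERalphaKO under placebo, with a median of -0.41 (adjusted p = 1.8e-04; adjusted p = 0.396 with an estimated correlation), at -0.68 without WT placebo replicate 1, at -0.15 without WT placebo replicate 2 (adjusted p = 0.159) and at -0.26 without ERalphaKO placebo replicate 3. Hypertrophy and mineralization genes lay at -0.22 (adjusted p = 6.0e-04; adjusted p = 0.330 with an estimated correlation), and at -0.13 without ERalphaKO placebo replicate 3, and Wnt ligands and antagonists lay at -0.24 (adjusted p = 0.00201; adjusted p = 0.0739 with an estimated correlation). Cell cycle genes lay at 0.43 (adjusted p = 2.32e-06; adjusted p = 0.403 with an estimated correlation) and at 0.26 without ERalphaKO placebo replicate 3. In all, 3 lists passed upward and 13 downward under placebo with the preset correlation, 0 with an estimated correlation, directional fry called 3, namely lymphocyte markers, Wnt ligands and sex steroid receptors, and mixed fry called 3. No member of these lists other than Esr1 was called by edgeR over all genes; in the 26 lists without Esr1, 50 of 378 members had an unadjusted p under 0.05 and DESeq2 called 12.

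Under E2, ERalphaKO fibrocartilage differed from WT in 163 genes, 67 higher and 96 lower (3 against 3 libraries). A2m was 75.7-fold lower, at 1.91 against 143 CPM (-6.24 ± 0.34, adjusted p = 1.63e-05), Greb1 67.9-fold lower (-6.09 ± 0.34, adjusted p = 1.63e-05), Sftpa1 150-fold lower (-7.23 ± 0.66, adjusted p = 4.49e-04) and Pi15 60.1-fold lower (-5.91 ± 0.40). Lgi2 was 72.0-fold, Myo5c 50.7-fold and Trpc6 32.8-fold lower. Hcn4 had 0 counts in the 3 ERalphaKO libraries and was at least 32.9-fold lower by the 95% counting limit. Against a floor of 3 counts over the group it was 40.9-fold lower. Ripk4 and Fam196b rested on 2 counts each in ERalphaKO, with count ratios of 65.8 (95% counting interval 18.0 to 548) and 45.2 (12.2 to 377). In the other direction, Limch1 was 6.14-fold higher (2.62 ± 0.24, adjusted p = 4.94e-04), the exocytosis gene Cadps2 3.39-fold (1.76 ± 0.18, adjusted p = 0.00114), D4Bwg0951e 4.41-fold and Tmem178 3.82-fold. Pik3c2g, a lipid kinase gene, was higher by 3.35 ± 0.48, the neural adhesion gene Chl1 by 2.45 ± 0.38, Frmd3 by 1.85 ± 0.29, Fetub by 1.80 ± 0.30 and the somatostatin receptor gene Sstr2 by 1.89 ± 0.37. Il7r, the receptor of interleukin-7 on lymphoid precursors, was higher by 3.52 ± 0.70 (adjusted p = 0.0435), in a comparison where lymphocyte markers were higher as well.

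Among list members under E2, Cytl1, a secreted protein of chondrocytes, stood at 77.6 CPM in ERalphaKO against 450 CPM in WT (-2.54 ± 0.43, adjusted p = 0.0210), and Sost, the osteocyte-derived Wnt antagonist sclerostin, was 4.06-fold lower (-2.02 ± 0.35, adjusted p = 0.0211). Sost also stood in the osteoblast and osteocyte marker list, which as a whole did not pass here with the preset correlation. The mean log2 CPM of that list was 8.029, 7.626 and 8.166 in WT E2 replicates 1 to 3. It was 7.843, 7.901 and 7.725 in ERalphaKO E2 replicates 1 to 3. Apart from marker lists, bone content was not tested. Adamts5 (-0.96 ± 0.15, adjusted p = 0.0138), Wnt4 (-0.91 ± 0.15, adjusted p = 0.0182) and the hypertrophy transcription factor gene Mef2c (-0.43 ± 0.08, adjusted p = 0.0354) were lower. Pgr rested on 1 count in ERalphaKO, with a count ratio of 51.2 (8.88 to 2050, adjusted p = 0.0175). Pappa, a protease of insulin-like growth factor binding proteins, was higher (1.36 ± 0.27, adjusted p = 0.0396), as were the tight junction gene Cldn10 (1.06 ± 0.20) and the Schwann cell transcription factor gene Sox10 (8.10-fold, 3.02 ± 0.47, adjusted p = 0.0129). Cldn10 came from the salivary gland markers and Sox10 from the peripheral nerve markers. The nerve list had a median of 0.17 (adjusted p = 0.0028 with the preset correlation), a call not kept with an estimated correlation. Its mean log2 CPM was 2.726, 2.859 and 2.32 in the ERalphaKO E2 libraries and 2.196, 1.713 and 1.698 in the WT E2 libraries. More nerve in the ERalphaKO libraries cannot be told apart. Of these 29 named calls, Pik3c2g, Limch1, D4Bwg0951e, Tmem178, Cadps2 and all 10 of the genes lower by size kept theirs without any one library. Of all 29, 15, 25 and 17 were kept without ERalphaKO E2 replicates 1 to 3, and 17, 26 and 19 without WT E2 replicates 1 to 3. In the other groups, 28, 24, 29 and 24 were kept without ERalphaKO placebo replicates 1 to 4, and 24 without either WT placebo library. Cytl1 lost its call without WT E2 replicate 1 or 3 or any one ERalphaKO E2 library, and Sost without replicate 1 or 3 of either group. Il7r kept its call in 2 of the 12 omissions, Mef2c and Pappa in 3, and Sstr2 and Cldn10 in 4. Each of those genes lost it without either WT placebo library, although those libraries are not part of this comparison.

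Counts of genes higher and lower under E2 became 16 and 35, 65 and 70, and 19 and 36 without ERalphaKO E2 replicates 1, 2 and 3. They became 26 and 42, 64 and 172, and 36 and 56 without WT E2 replicates 1, 2 and 3. They became 39 and 71 and 43 and 70 without ERalphaKO placebo replicates 2 and 4, and 36 and 67 and 36 and 68 without WT placebo replicates 1 and 2. DESeq2 called 245 genes higher and 252 lower, including all 163. With the muscle marker level as a covariate edgeR called 25 higher and 57 lower. It called 26 and 44 without the 2 libraries of the highest granulocyte marker level, a setting chosen after the data were seen.

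As groups under E2, cartilage matrix genes lay at a median of -1.70 in ERalphaKO against WT with 6 of 20 lower when adjusted over the list alone (adjusted p = 6.95e-07; adjusted p = 0.322 with an estimated correlation), and at -0.52 without WT E2 replicate 3. The mean log2 CPM of this list was 7.78 in WT E2 replicate 3 and 6.49 and 6.42 in WT E2 replicates 1 and 2, while granulocyte markers in that library stood at 4.31. Hypertrophy and mineralization genes lay at -0.40 with 6 of 15 lower when adjusted over the list alone (adjusted p = 3.37e-05; adjusted p = 0.322 with an estimated correlation), and at -0.25 without WT E2 replicate 3. Macrophage markers lay at -0.61 with 7 of 14 lower when adjusted over the list alone (adjusted p = 6.95e-07; adjusted p = 0.322 with an estimated correlation), and at -0.35 without WT E2 replicate 3. Interferon response genes lay at -0.58 (adjusted p = 3.2e-04; adjusted p = 0.461 with an estimated correlation) and lost the call without WT E2 replicate 3 (median -0.21, adjusted p = 0.121). Lymphocyte markers lay at 4.02 with 11 of 13 higher when adjusted over the list alone (adjusted p = 1.36e-11; adjusted p = 0.317 with an estimated correlation), and at 2.43 without ERalphaKO E2 replicate 1. Their mean log2 CPM was 3.41, -0.70 and 1.74 in the ERalphaKO E2 libraries. Muscle markers lay at -4.10 (adjusted p = 1.82e-10; adjusted p = 0.324 with an estimated correlation), and granulocyte markers at 2.24 (adjusted p = 0.00136; adjusted p = 0.505 with an estimated correlation), a call that ended without ERalphaKO E2 replicate 1 (median -0.70, adjusted p = 0.142). Without WT E2 replicate 3 the granulocyte median was 8.69 (adjusted p = 9.24e-08). Erythroid markers lay at 4.02 with 7 of 7 positive (adjusted p = 0.0179; adjusted p = 0.445 with an estimated correlation), and their call ended without ERalphaKO E2 replicate 3 (median 0.54, adjusted p = 0.728) and without WT E2 replicate 3 (adjusted p = 0.0522). By edgeR 0 of those 7 were called over all genes, 5 had an unadjusted p under 0.05 and DESeq2 called 0. With the preset correlation 6 lists passed upward and 9 downward, and 0 with an estimated correlation or by directional fry, while mixed fry called 16.

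The difference of the E2 effect between genotypes was tested directly as an interaction. It passed for 8 genes. The response was larger in WT for Greb1 (5.85 ± 0.56, adjusted p = 0.00862), Gbp8 (4.89 ± 0.61, adjusted p = 0.0250), Pi15 (4.29 ± 0.56, adjusted p = 0.0292), Trpc6 (4.21 ± 0.49, adjusted p = 0.0202), Gbp4 (3.66 ± 0.41, adjusted p = 0.0202), Thbs1 (2.01 ± 0.25, adjusted p = 0.0250) and Whrn (1.67 ± 0.23, adjusted p = 0.0327). For Slc20a2 it was -1.31 ± 0.18 (adjusted p = 0.0429), a fall in WT against 147 and 161 CPM under placebo and E2 in ERalphaKO. Among single omissions, Greb1 lost its call without WT placebo replicate 1 (adjusted p = 0.0598), and the other 7 were kept in between 2 and 6 of the 12 omissions. Of the 8 calls, 0 were kept without WT placebo replicate 1, where 711 genes had an unadjusted p under 0.05 by edgeR, and 1 was kept without WT placebo replicate 2, WT E2 replicate 3 or any one ERalphaKO E2 library, 3 without ERalphaKO placebo replicate 4, 4 without ERalphaKO placebo replicate 1, 5 without WT E2 replicate 1 and 6 without ERalphaKO placebo replicate 2. The count of genes with a larger response in WT was 28 without WT E2 replicate 2, 16 without ERalphaKO placebo replicate 3, 4 without WT E2 replicate 1 or ERalphaKO placebo replicate 1, and 3 without ERalphaKO placebo replicate 4. DESeq2 gave 57 genes in that direction and 45 in the other, and 1005 genes had an unadjusted p under 0.05 in edgeR. With the muscle marker level as a covariate edgeR called 0 genes, 1072 had an unadjusted p under 0.05, and Greb1 had an adjusted p = 0.0945, while its log2 difference was 5.35 against 5.85 without the covariate. That of Gbp8 was 4.995 with it, of Pi15 4.097, of Trpc6 4.199, of Gbp4 3.732, of Thbs1 1.853, of Whrn 1.848 and of Slc20a2 -1.256.

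Among lists, the interaction placed macrophage markers at a median of 0.83 with 6 of 14 members larger in WT when adjusted over the list alone (adjusted p = 2.04e-07; adjusted p = 0.581 with an estimated correlation), and at 0.53 without ERalphaKO placebo replicate 3. All 18 interferon response genes were positive, with a median of 0.80 (adjusted p = 6.57e-06; adjusted p = 0.611 with an estimated correlation), at 0.37 without WT E2 replicate 3 and at 0.32 without ERalphaKO placebo replicate 3. All 19 skeletal muscle markers were positive as well, with a median of 4.62 (adjusted p = 1.24e-11; adjusted p = 0.581 with an estimated correlation), and 11.3 without WT placebo replicate 2. In all 6 lists passed upward and 4 downward, 0 with an estimated correlation or by directional fry. Mixed fry called 3, the estrogen-responsive list (adjusted p = 8.84e-05), the insulin-like growth factor axis (adjusted p = 0.00788) and sex steroid receptors (adjusted p = 0.0470).

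**Figure D3:**
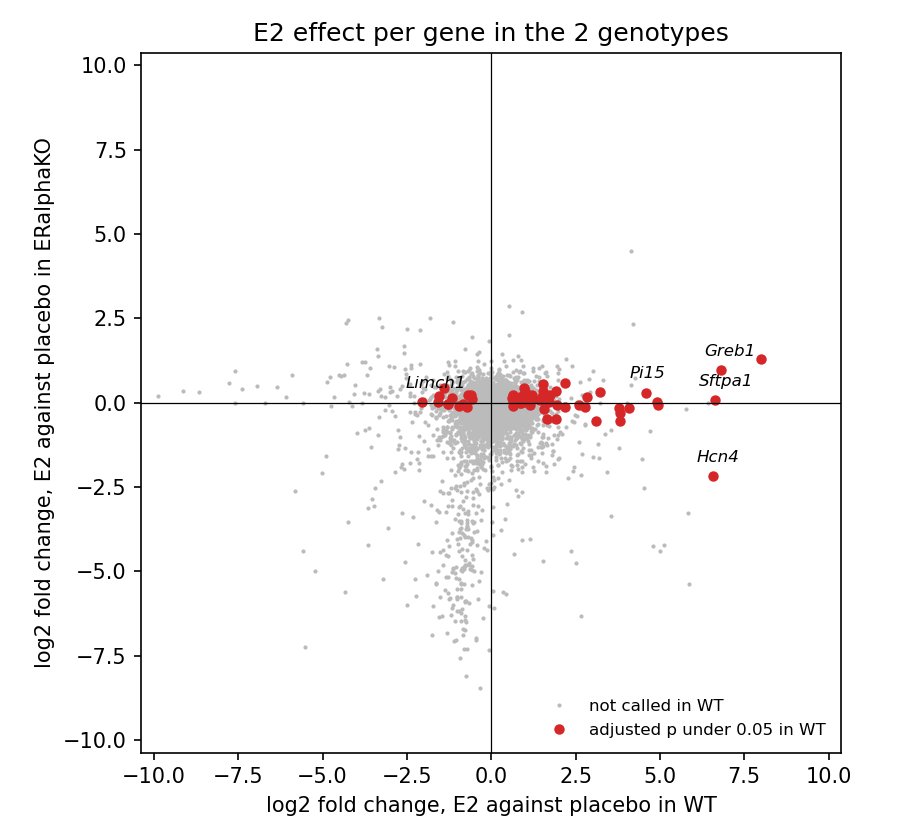
Each point is 1 of the 14832 genes tested, with its log2 fold change with E2 in WT on the horizontal axis and in ERalphaKO on the vertical axis; red points are the 68 genes called in WT, and Greb1, Pi15, Sftpa1, Hcn4 and Limch1 are named. The red points had medians in ERalphaKO of 0.079 for those higher and 0.0328 for those lower in WT, and ranged there from -2.18 for Hcn4 to 1.30 for Lgi2, neither of which was called in ERalphaKO.

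Across the 14832 genes, the E2 effects in WT and in ERalphaKO had a Pearson correlation of 0.122 and a Spearman correlation of 0.0344, with genes not being independent replicates. Without WT placebo replicate 2 the Pearson correlation was -0.459. The 55 genes that rose in WT had a median of 1.52 there and of 0.079 in ERalphaKO, and the 13 that fell had -1.17 and 0.0328. Of these 68 genes, 41 had the same sign in ERalphaKO and 4 of those had an unadjusted p under 0.05. Genotype effects under placebo and under E2 correlated at 0.391 (Pearson) and 0.216 (Spearman) across genes, at -0.0966 (Pearson) without WT placebo replicate 2 and at 0.14 without ERalphaKO E2 replicate 1. A2m was called lower in both, where 0.0129 genes were expected by chance for independent lists. Neither pair of comparisons shared a library.

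The authors' deposited table of WT under E2 against WT under placebo listed 256 genes with adjusted p under 0.05, 170 higher and 86 lower, and all 68 edgeR calls were among them. The authors' deposited table of ERalphaKO against WT under placebo listed 270 genes, 224 higher and 46 lower, and that of ERalphaKO against WT under E2 listed 545, 186 higher and 359 lower. In the authors' deposited table under placebo, the lymphocyte markers Vpreb3 (log2 fold change 5.793), Cd79b (4.987) and Cd79a (3.98) were among the genes of smallest adjusted p. So was A2m, which was lower (-3.266). The authors' deposited table of E2 in ERalphaKO listed 9 genes, of which Ifitm5, a bone-restricted membrane protein gene, Nbl1, a BMP antagonist gene, and Aplnr, the apelin receptor gene, were higher. The other 6 genes in the authors' deposited table were lower, among them Rbm24 and Scn4a, both known from striated muscle, and the clock gene Arntl. In the authors' deposited tables of groups that differ in both genotype and treatment, 77 genes differed between ERalphaKO under E2 and WT under placebo, and 932 between ERalphaKO under placebo and WT under E2.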

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

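Of the tests in this part, those of shared reads over all called Gbp genes and of muscle in the authors' deposited table were written down before their results were seen; the other tests were chosen after.

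Among 31 values tested for the 4 ERalphaKO placebo libraries, 3 marker or list scores had a single library far from the rest. Chance flags about 1 in 20 groups. The cell cycle score of ERalphaKO placebo replicate 3 was 5.126 and its endothelial score 5.232, and the epithelial score of ERalphaKO placebo replicate 1 was -0.7691.

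The test of the difference between genotypes marked 8 genes as responding to E2 differently in WT and in ERalphaKO: Greb1 (5.85), Gbp8 (4.89), Pi15 (4.29), Trpc6 (4.21), Gbp4 (3.66), Thbs1 (2.01), Whrn (1.67) and Slc20a2 (-1.31). It also marked 10 lists with the preset correlation, by median difference: skeletal muscle markers (4.62), lymphocyte markers (1.247), macrophage markers (0.8269), interferon response (0.8047), inflammatory and NF-kB (0.4614), endothelial markers (0.2263), peripheral nerve markers (-0.1749), insulin-like growth factor axis (-0.2418), fibrous matrix (-0.2569) and Wnt target genes (-0.276). None of the 10 passed with an estimated correlation or by directional fry, and by mixed fry the growth factor axis did (adjusted p = 0.00788). In single omissions the muscle median was 11.3 without WT placebo replicate 2, the macrophage median 0.53 without ERalphaKO placebo replicate 3, and the interferon median 0.37 without WT E2 replicate 3 and 0.32 without ERalphaKO placebo replicate 3, with these 3 calls kept. The lymphocyte median was 0.77 and 0.63 without WT E2 replicates 1 and 3, and 2.54 and 0.78 without ERalphaKO E2 replicates 1 and 3, and the call ended without ERalphaKO E2 replicate 2 (adjusted p = 0.102).

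The other 6 lists of that test also depended on single libraries. The inflammatory call ended without WT placebo replicates 1 and 2 (adjusted p = 0.0666 and 0.313), WT E2 replicate 3 (median 0.049, adjusted p = 0.756), ERalphaKO placebo replicates 3 and 4 (median 0.25 and 0.41, adjusted p = 0.174 and 0.143) and ERalphaKO E2 replicate 2 (median 0.24, adjusted p = 0.157). The endothelial call ended without WT placebo replicate 2 (median 0.12, adjusted p = 0.364), WT E2 replicates 1 and 3 (median 0.17 and 0.03, adjusted p = 0.16 and 0.693), ERalphaKO placebo replicate 3 (median 0.14, adjusted p = 0.105) and ERalphaKO E2 replicates 1 and 2 (adjusted p = 0.0571 and 0.102), and the median was 0.44 without WT E2 replicate 2. The peripheral nerve call ended without WT placebo replicate 2 (adjusted p = 0.108), WT E2 replicates 2 and 3 (median -0.12 and -0.34, adjusted p = 0.155 and 0.0789), ERalphaKO placebo replicates 3 and 4 (median -0.23 and -0.27, adjusted p = 0.115 and 0.0636) and ERalphaKO E2 replicates 1 and 2 (median -0.41 and -0.23, adjusted p = 0.0889 and 0.128). Its median was -0.45, -0.37 and -0.31 without WT E2 replicate 1, ERalphaKO placebo replicate 2 and ERalphaKO E2 replicate 3. The growth factor call ended without WT placebo replicate 2 (adjusted p = 0.0504), WT E2 replicates 2 and 3 (median -0.22 and -0.12, adjusted p = 0.155 and 0.0619), ERalphaKO placebo replicates 3 and 4 (adjusted p = 0.105 and 0.0594) and ERalphaKO E2 replicates 1 and 2 (adjusted p = 0.0565 and 0.102). Its median was -0.09 without WT placebo replicate 1 and -0.14 without ERalphaKO placebo replicate 1. The fibrous matrix call ended without WT E2 replicate 3 (median -0.10, adjusted p = 0.069), ERalphaKO placebo replicate 3 (adjusted p = 0.0925) and ERalphaKO E2 replicate 2 (median -0.14, adjusted p = 0.0611), and its median was -0.39 and -0.14 without ERalphaKO E2 replicates 1 and 3. The Wnt target call ended without ERalphaKO placebo replicate 3 (median -0.15, adjusted p = 0.0657), and its median was -0.18 without ERalphaKO E2 replicate 3.

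Lymphocyte markers stood higher in ERalphaKO than in WT libraries, apart from ERalphaKO E2 replicate 2, where their mean log2 CPM was -0.70. Marrow or blood of a constant makeup carried into the samples was argued against by a fit with granulocyte and erythroid scores as covariates. There the median under placebo was 4.92 ± 1.11, against 4.94 without, and 12 of 13 members were higher. The ± is a standard error over the 13 members and does not measure the spread between libraries. A wrong label on ERalphaKO E2 replicate 2 was argued against by its A2m level of 1.89 CPM, where the lowest WT library had 18.5 CPM. An exact permutation test of genotype within treatment gave p = 0.00667 (5 WT and 7 ERalphaKO libraries, 300 arrangements), but the list was picked from 27 after its scores were seen, and adjusted for that choice the permutation p was 0.18, where the smallest possible was 0.09. That test decides nothing, so genotype stays open, as does a piece of marrow with another makeup, which was not tested.

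In the neighbourhood of Gbp4, 4 of 5 Gbp genes rose with E2 in WT, Gbp10 not being called, and the median of the 5 was 3.12. An interferon response that raised all Gbp genes alike was argued against by the other Gbp neighbourhood, whose median was 0.293. Its 4 genes, all positive and none called, ranged from 0.19 ± 0.56 for Gbp3 to 0.87 ± 0.52 for Gbp5. The 2 neighbourhoods were set against each other after their values were seen. The interferon response list itself lay at 0.57, so a weaker general response stays open. A larger share of all macrophages alike was argued against by the macrophage median of 0.79 ± 0.142 (standard error over members). A larger subset of macrophages with high Gbp levels was not tested. Reads from identical stretches were argued against for Gbp4, Gbp8 and Gbp9, of whose 100-base stretches at least 95.6% occur in no other gene. For Gbp6 the share was 35.5% and for the uncalled Gbp10 26.5%, so reads from paralogs cannot be told apart there. Stretches that differ from a paralog by a few bases were not tested, and the treatment of reads with several matches was not given. Reads placed on a similar paralog with mismatches therefore stay open for all of these genes. Regulation of this neighbourhood through estrogen receptor alpha is a hypothesis, found and tested on the same data.

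In the authors' deposited table of E2 in ERalphaKO, 9 genes were called. With the muscle score as a covariate DESeq2 called 0 of them, but without it 3 of 9, so the test had little to lose and for the 9 as a set muscle carried into some libraries cannot be told apart. With the covariate 5 of the 9 hardly moved: Arntl from -1.02 to -1.06, LOC433374 from -3.08 to -3.07, Nbl1 from 0.30 to 0.27, Aplnr from 0.37 to 0.33 and Ifitm5 from 0.51 ± 0.12 to 0.52 ± 0.15. Scn4a moved from -3.62 ± 1.052 to -1.95 ± 0.901 and Itgb1bp2 from -4.51 ± 1.12 to -2.18 ± 0.88, neither called by DESeq2 without the covariate. Of the 3 that were, which include Ifitm5, Rbm24 moved from -5.53 ± 1.17 to -4.25 ± 1.11 and Nsg2 from -3.09 ± 0.68 to -2.52 ± 0.74. WT placebo replicates 1 and 2 had muscle scores of -0.62 and 6.74, with Rbm24 at 0 and 5.46 CPM. There Scn4a stood at 0 and 4.54, Itgb1bp2 at 0.23 and 3.85 and LOC433374 at 0 and 0.62 CPM. Arntl, Nbl1, Ifitm5, Nsg2 and Aplnr were lower in replicate 2. Rbm24, Scn4a and Itgb1bp2 thus followed the muscle score without E2, in 1 library at each level.

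For E2 in ERalphaKO the real split called 0 genes by edgeR (846 with an unadjusted p under 0.05, 5 called by DESeq2), so all 35 splits of the 7 libraries had to reach that count and it says nothing about chance; the highest other split called 1. For genotype under E2, 1 of 10 splits, the real one, called as many as 163 genes and the highest other called 0; the splits are too few for a share under 0.05.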

How the results depend on the processing

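The 2-covariate fit, voom with library weights and the omission of the 2 libraries with the highest granulocyte markers were chosen after seeing the data; the other settings were planned. No called named gene changed direction in any of the 22 settings. Of 61 such calls, DESeq2 kept 61, size factors 60, no filter 60, robust estimation 59, voom 57, omission of the 2 granulocyte-rich libraries 44, both covariates 43, the muscle covariate 31, the replicate block 27, and fits to the 2 groups 18 of 53. Single omissions kept 473 of 732. Of 59 list calls an estimated correlation kept 0 and directional fry 3. In smaller libraries 3 counts were 0.309 CPM, which limits genes near that level. The cause of the changes was not tested, except that fewer libraries leave fewer degrees of freedom.

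Genes higher and lower for E2 in WT were 157 and 90 by DESeq2, 7 and 0 with the 2 groups alone, 15 and 3 with the block, 36 and 9 with the muscle covariate, 72 and 26 with both covariates, and 118 and 51 by voom; single omissions gave 1 to 113 and 0 to 18. For E2 in ERalphaKO DESeq2 gave 1 and 4 and both covariates 0 and 6, and single omissions 0 and 0 throughout. For genotype under placebo DESeq2 gave 123 and 27, the 2 groups alone 0 and 0, the block 0 and 0 (A2m adjusted p = 0.0782), the muscle covariate 0 and 1, both covariates 1 and 3, voom 1 and 3, and omission of the 2 granulocyte-rich libraries 52 and 5; single omissions gave 0 to 2 and 1 to 2.

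For genotype under E2 the counts were 245 and 252 by DESeq2, 10 and 56 with the 2 groups alone, 19 and 43 with the block, 25 and 57 with the muscle covariate, 34 and 83 with both, 137 and 231 by voom, and 26 and 44 without the 2 granulocyte-rich libraries; single omissions gave 16 to 82 and 35 to 172. For the interaction they were 57 and 45 by DESeq2, 3 and 0 with the block, 0 and 0 with the muscle covariate (Greb1 5.35 against 5.85, Trpc6 4.199 against 4.21), 10 and 3 with both, 25 and 5 by voom, and 11 and 1 without the 2 granulocyte-rich libraries; single omissions gave 0 to 28 and 0 to 3. The correlation of the E2 effects was -0.116 with the muscle covariate, -0.0867 with both, -0.163 by voom and -0.459 to 0.215 in single omissions. That of the genotype effects was 0.206 without the filter and -0.0966 to 0.508 in single omissions.

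List tests changed direction as follows. Muscle markers gave medians of -0.1014 and -0.06456 for E2 in ERalphaKO with the muscle covariate and with both, 0.03445 and 0.001193 for genotype under E2, and 0.0115 and 0.003287 for the interaction, which follows from using their own score. With both covariates granulocyte markers gave -0.7921 and -0.2133 for genotype under placebo and E2, for the same reason. Immediate-early genes gave 0.1902 for E2 in ERalphaKO with the block. In single omissions muscle markers ranged from -1.833 to 5.68 for E2 in WT and from -0.9299 to 7.301 for genotype under placebo, where the test turned without WT placebo replicate 1 (-0.3253). Immediate-early genes ranged from -0.6716 to 0.06037 for E2 in WT, -0.3109 to 0.2015 for E2 in ERalphaKO and -0.7047 to 0.5904 for genotype under placebo. Interferon genes (-0.4172 to 0.04554) and erythroid markers (-3.256 to 0.9162) for E2 in ERalphaKO, and adipocyte markers (-3.343 to 0.9593) for genotype under placebo, turned as well. The labels give no meaning to replicate numbers, and they were not taken to pair samples, since 9 of 15 same-numbered pairs and not all had a correlation above 0.1 (-0.326 to 0.5). Their median was 0.203, against -0.0338 for differently numbered pairs, and the 6 pairs numbered 2 lay at 0.215 to 0.47, so a factor shared by the libraries numbered 2 stays open. Each library numbered 2 had the lowest granulocyte score of its group. These scores were 0.73 in WT placebo, -1.92 in WT E2, -0.10 in ERalphaKO placebo and -0.42 in ERalphaKO E2. Whether that accounts for the correlation was not tested. Of 12 libraries 6 correlated best with their own number. DESeq2 gives no list test.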

Other observations

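The genes of this part were chosen after their values were seen. Siglec1, the macrophage sialic acid receptor sialoadhesin, rose with E2 in WT and stood at 11.3 and 9.6 CPM in the WT placebo libraries and at 43.5, 29.6 and 69.2 CPM in the WT E2 libraries (2.18 ± 0.31, adjusted p = 0.0171), and lost its call without WT placebo replicate 1 or 2 or WT E2 replicate 1. In ERalphaKO it averaged 7 CPM under placebo and 6.37 CPM under E2. Under E2 the fractalkine receptor gene Cx3cr1 was lower in ERalphaKO than in WT (-1.59, adjusted p = 0.0182), as was Cilp, a cartilage intermediate layer protein gene (-1.70, adjusted p = 0.0224). Both lost their calls without WT E2 replicate 1 or any one ERalphaKO E2 library, and Cilp also without WT E2 replicate 3.

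Rag1, which cuts antigen receptor genes in lymphoid precursors, stood at 75.5, 62.6, 18.6 and 45.0 CPM in ERalphaKO placebo replicates 1 to 4 and at 29.3, 0.0 and 7.3 CPM in ERalphaKO E2 replicates 1 to 3, and at no more than 0.7 CPM in any WT library. The circadian clock genes Arntl and Dbp were called in none of the 5 comparisons by edgeR, while the authors' deposited table of E2 in ERalphaKO called Arntl (-0.98, adjusted p = 0.00391). Arntl stood at 31.8, 15 and 6.8 CPM in WT E2 replicates 1 to 3, and Dbp at 73.6, 188 and 236 CPM. Times of sampling were not given in the sources used here.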
